A study of Cricetulus griseus with 3 samples.

How the data were processed

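RNA was extracted with a Qiagen RNeasy kit, selected for poly-A tails with an Exiqon dT locked nucleic acid kit and made into libraries with the Illumina TruSeq RNA version 2 kit, per the labels' protocols. The 3 samples, interphase microtubules, mitotic microtubules and midbodies, were grouped by their titles, 1 library per group. The columns headed Metaphase were taken as the sample titled Mitosis, the only sample of that stage. The aligner, the counting program, the genome build and any filter of the authors are not given in the sources used here.

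The deposited table lists 21607 RefSeq transcripts with 3 kinds of values. Estimated counts of reads per transcript are the authors' unnormalized values, fractional in 15.9% of transcripts for midbodies, 16.9% for mitotic and 14.9% for interphase, as when a read is divided between transcripts. RPKM, reads scaled by transcript length and library total, was computed by the authors, per the file headers. Dividing the deposited RPKM by the deposited reads gave 1 whole-number length per transcript with the column total as library size. The authors also paired 20821 transcripts with their best human protein by BLASTX, per the file headers, with E-values of at most 1e-20. Enrichment scores that the authors derived from RPKM were not used here. Strand was not stated, so reads of overlapping and antisense genes may be mixed, and reads shared between paralogs, as in the tubulin and ribosomal protein families, make single members uncertain.

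Gene symbols came from NCBI RefSeq assembly CriGri-PICRH-1.0, matched by transcript accession and used for names only. They matched 311 transcripts, 293 by exact version and 18 by another version of the accession, which gave 304 named genes. All other transcripts kept their identifiers, so most genes of the table are unnamed here and no coordinates are given. Where a symbol had 2 transcripts, the transcript with more reads was used. Of these, the reads of Xbp1 were divided almost evenly.

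Ratios were taken on the log2(RPKM + 1) scale, which understates differences of low transcripts, over transcripts at 1 RPKM or more in at least 1 of the compared libraries. Folds and factors quoted with an interval are plain ratios of the reads after division by the library total (CPM), with exact binomial (Clopper-Pearson) 95% intervals. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. A count of 0 allows up to 3 reads, which is 0.584 CPM in midbodies, 0.372 in mitotic and 0.237 in interphase microtubules. The midbody library is the shallowest and its ratios of low transcripts are the least precise. To show what counting noise alone gives, 100 sets of unchanged libraries were drawn from a Poisson model at the observed depths. The procedure was tested on simulated data with 200 changed transcripts per comparison. For midbodies against mitotic microtubules, it recovered 98% of 3-fold increases and 92% of 3-fold decreases. Among the 12937 transcripts compared there, 67 unchanged ones also passed 2-fold. The changed transcripts came from those at 1 RPKM or more in both libraries and the noise was Poisson only. Recovery of lower transcripts was therefore not tested.

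The design, gene lists, naming rule and first set of alternatives were fixed before the data were examined. Named genes were, per comparison, the 10 highest and 10 lowest ratios among genes with a symbol at 10 RPKM and 50 reads in the higher library, the 10 genes with the highest smaller ratio of midbodies over both other libraries, up to 4 members of each list with the largest absolute ratios, the 10 most abundant transcripts of each library where they had a symbol, and Kif23. Other list members quoted complete a group. Of 23 preset gene lists, 8 had 3 or more named members and were summarised by their median and its percentile among 10000 random lists of the same size, drawn within 20 expression bins. A list among these and some single genes are not reported here. Another 7 lists had 1 or 2 members and are given by gene: central spindle and midbody proteins (Kif23), immediate early genes (Fos), translation factors, respiratory chain, actin cytoskeleton (Actb), p53 targets (Bax) and RNA granule proteins (Fxr1). The other 8 lists had no named member and gave no value: ESCRT and abscission, septins, pluripotency factors, mitochondrially encoded genes, microtubule-associated proteins, replication-dependent histones, nuclear-retained RNAs and markers of other cell types. A further 7 lists were written after gene names and the extreme ratios had been seen.

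Alternatives were pseudocounts of 0.1 and 5, no expression filter and a filter at 10 RPKM, median of ratios scaling, trimmed mean of M values scaling with 30% of ratios and 5% of abundances trimmed, CPM in place of RPKM, transcripts with a symbol only, and unmatched random lists. Random lists matched on transcript length as well were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.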

Results

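Poly-A RNA was sequenced from microtubules isolated from CHO cells, a Chinese hamster (Cricetulus griseus) ovary line, at 3 points of the cell cycle. Interphase microtubules came from cells held in 2 mM thymidine, which arrests DNA synthesis, for 16 h. Mitotic microtubules came from cells released from thymidine for 5 h, held in nocodazole, a drug that blocks microtubule assembly, at 0.1 ug/ml for 4 to 5 h, shaken off the dish and given 15 min of fresh medium. Midbodies, the microtubule bridges left between daughter cells at the end of division, were prepared like the mitotic sample but with 65 min of fresh medium. The comparisons ask which RNAs distinguish the midbody from spindle and interphase microtubules. No whole-cell RNA was among the 3 samples, so RNA held on these structures cannot be told apart from RNA abundant in the cells. The longer time of the midbody sample in fresh medium cannot be told apart from the structure isolated either. Each group had 1 library, so no difference has a replicate check and no p-value is given. Intervals below are exact 95% binomial intervals on the read counts and cover counting error only.

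The midbody library held 5134865 assigned reads, the mitotic library 8059745 and the interphase library 12672056. Of 21607 RefSeq transcripts, 12773 reached 1 RPKM in the midbody library, 12883 in the mitotic library and 12255 in the interphase library. Gapdh, a glycolytic enzyme gene, was among the 10 most abundant transcripts of every library, at 548, 605 and 704 RPKM in midbody, mitotic and interphase order. Csr1 headed the midbody and mitotic libraries with 1841 and 1342 RPKM. Actb, which encodes cytoplasmic actin, headed the interphase library with 1054 RPKM. The translation elongation factor gene Eef1a1, the ribosomal protein gene Rps2 and the chaperone gene Hspa8 were in the interphase top 10 with 707, 594 and 448 RPKM. Reads of Gapdh, Csr1, Actb and Eef1a1 were partly shared with other transcripts, so their levels are less certain. Of the 10 leading transcripts, the midbody and mitotic libraries shared 8 and all 3 libraries shared 4. Across 13325 transcripts, which are not independent replicates, Spearman's rho was 0.971 between midbody and mitotic RPKM, 0.808 between midbody and interphase, and 0.785 between mitotic and interphase.

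Kif23, the motor subunit of the centralspindlin complex and a standard midbody protein, stood at 274 RPKM in the midbody library, 109 in the mitotic library and 79.0 in the interphase library. Its RNA was 2.51-fold higher in midbodies than in mitotic microtubules (interval 2.40 to 2.63). Fos, an immediate early transcription factor gene, showed the highest midbody to mitotic ratio among named genes, 10.3-fold (interval 8.71 to 12.1), from 188 against 18.3 RPKM. Gpx1, which encodes a selenium-containing glutathione peroxidase, was 6.07-fold higher (4.68 to 7.94), though its 62.6 RPKM in midbodies was below the 115 in interphase. The chemokine gene Cxcl1 was 3.49-fold higher (3.18 to 3.83). Rcan1, a calcineurin regulator, and Icam1, an adhesion molecule gene, were higher by 3.10-fold (2.79 to 3.44) and 2.85-fold (2.65 to 3.07).

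In all, 8 of 234 named genes past the expression floor were at least 2-fold higher in midbodies than in mitotic microtubules on the log2(RPKM + 1) scale, and 0 were at least 2-fold lower. The other high members were Sat1, a polyamine acetyltransferase gene, with a log2 ratio of 1.05, and the carbonyl reductase gene Cbr3 with 1.03, which fell to 0.81 with a pseudocount of 5. Just under the line stood Gna13, a G protein alpha subunit gene, with 0.995, which became 1.01 under median of ratios scaling, and the phosphate transporter gene Slc20a1 with 0.92. The lowest named genes included the amino acid transporter gene Slc1a4 at -0.91, the RNA polymerase II subunit gene Polr2a at -0.84, the transcription factor gene Xbp1 at -0.82, the galactosyltransferase gene B4galt2 at -0.81, the protease gene Furin at -0.72 and the O-GlcNAc transferase gene Eogt at -0.67. Reads of Cbr3, Slc20a1, Xbp1 and Furin were partly shared with other transcripts, so their ratios are less certain.

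Insig1, a sterol sensor, and Srebf2, the sterol-response transcription factor gene, were lower in midbodies than in mitotic microtubules by less than 2-fold. The factors were 1.96 (1.73 to 2.23) for Insig1 and 1.86 (1.68 to 2.05) for Srebf2. Of the 6 tubulin genes, 4 were higher and 2 lower, from Tubb4b at 0.91 to Tubb at -0.68, with a median of 0.32 at percentile 95.7. Tubulin genes are close paralogs and all 6 carried shared reads. The 3 heat shock genes Hsp90aa1, Hspa8 and Hsph1 had log2 ratios of 0.33, 0.27 and 0.82 and a median at percentile 86.9. The 7 ribosomal protein genes included Rps13 at -0.31 and Rps2 at 0.43 and had a median of 0.26 at percentile 83.0.

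All 3 genes of the G2 phase and mitosis were slightly higher in midbodies than in mitotic microtubules. Top2a, which encodes the mitotic DNA topoisomerase, had a log2 ratio of 0.28, the centromeric histone gene Cenpa 0.28 and the kinesin gene Kif2c 0.12, with a median at percentile 81.9. The 5 S phase genes had a median of 0.07 at percentile 59.1, with Pcna, the replication clamp gene, highest at 0.53. The 8 endoplasmic reticulum stress genes had a median of 0.01 at percentile 25.4, and Hspa5, the luminal chaperone gene BiP, was at 201 RPKM in both libraries. The 4 genes of secreted and membrane proteins had a median of -0.00 at percentile 39.2, a value whose sign turned with the scaling. Among groups with fewer than 3 measured members, the elongation factor genes Eef2 and Eef1a1 were at 0.14 and 0.13, the respiratory chain gene Ndufa1 at 0.64, Actb at 0.04, the proapoptotic gene Bax at 0.30 and the RNA granule gene Fxr1 at 0.07.

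Across all 13131 compared transcripts, 274 were at least 2-fold higher and 237 at least 2-fold lower in midbodies than in mitotic microtubules. At 4-fold the counts were 24 and 6, or 81 and 82 with a pseudocount of 0.1 and 11 and 0 with a pseudocount of 5. The median log2 ratio was -0.03. The counting interval excluded a ratio of 1 for 258 of the 274 and 177 of the 237. In 100 Poisson draws from unchanged libraries at these depths, the mean counts were 30.2 higher and 38.6 lower. Raising the pseudocount to 5 left 99 and 31 transcripts at 2-fold, and lowering it to 0.1 turned the balance to 458 higher and 479 lower. Most transcripts have no symbol here. Chosen after their values were seen, XM_003499390.1 (best human protein match P04141) was 16.6-fold higher (11.3 to 25.2) and XM_003511578.1 (P18847) 14.7-fold higher (10.6 to 20.9), whereas XM_003509860.1 (O95125) was lower by a factor of 6.71 (4.07 to 11.8) and XM_003502687.1 (Q8N4L8) by 6.19 (2.85 to 16.0).

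**Figure D1:**
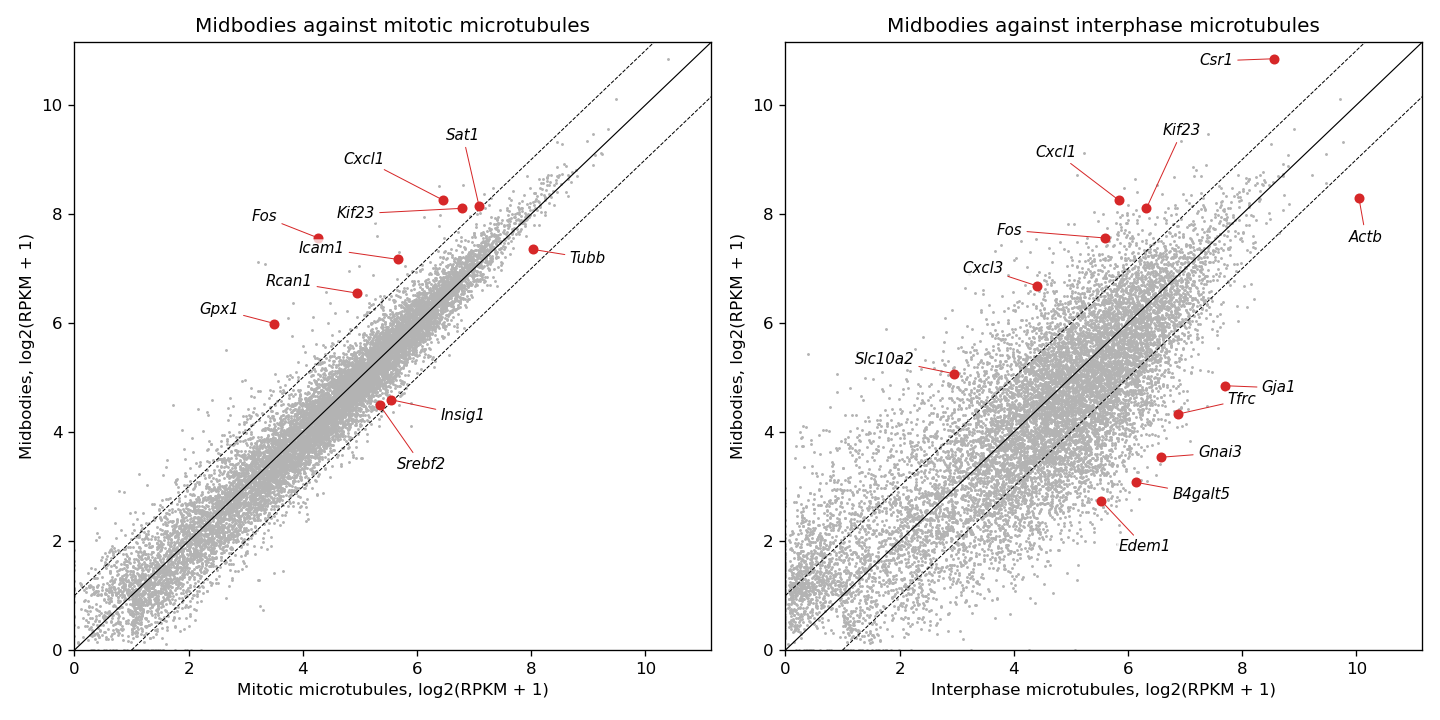
Each grey point is a transcript, with the midbody level on the vertical axis and the mitotic (left) or interphase (right) level on the horizontal axis, all as log2(RPKM + 1), and red points are named genes. The solid line marks equal levels and the dashed lines 2-fold differences: the left cloud is narrow, with 274 transcripts above and 237 below the 2-fold lines, and the right cloud is wide, with 1921 above and 2712 below.

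Against interphase microtubules, the midbody library was higher for Cxcl1, by 5.40-fold (4.93 to 5.92), for Fos by 3.97-fold (3.60 to 4.37) and for Kif23 by 3.47-fold (3.32 to 3.63). Rad52, of homologous recombination, was higher by 2.70-fold (2.39 to 3.05), and Xrcc1, of single-strand break repair, by 2.70-fold (2.52 to 2.89). B4galt5, a galactosyltransferase gene, was lower in midbodies by a factor of 9.29 (6.95 to 12.7), the G protein gene Gnai3 by 8.94 (6.87 to 11.8), the copper transporter gene Slc31a1 by 9.13 (6.07 to 14.4) and Gja1, a gap junction connexin gene, by 7.43 (6.47 to 8.58).

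Of 257 named genes past the floor, 17 were at least 2-fold higher and 78 at least 2-fold lower in midbodies than in interphase microtubules. Ankrd1, an ankyrin repeat gene, had a log2 ratio of 1.60. Csr1, Cxcl3 and the bile acid transporter gene Slc10a2 had 2.29, 2.27 and 2.11, and their reads were partly shared with other transcripts. Among the lowest were the vesicle fusion gene Sec22b at -2.94, the GDP-fucose transporter gene Slc35c1 at -2.94, the pyruvate dehydrogenase gene Pdha1 at -2.83, and the G protein genes Gnai1 and Gna11, both at -2.77. Named genes as a set sat lower than the rest of the table: the median log2 ratio was -0.49 over 282 transcripts with a symbol and -0.15 over all 13059 compared transcripts, the last of which turned to 0.02 without the expression filter.

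Of 8 endoplasmic reticulum stress genes, 4 were at least 2-fold lower in midbodies than in interphase microtubules: Edem1, of misfolded protein disposal, at -2.80, Xbp1 at -1.49, the lectin chaperone gene Canx at -1.44 and the disulfide isomerase gene Pdia3 at -1.09. The stress transcription factor gene Atf4 was at 0.74. The median of -0.97 lay at percentile 0.07 of random lists but at percentile 3.25 of random lists of named genes, inside their central 95%, as it was with unmatched random lists. In the group of secreted and membrane proteins, the transferrin receptor gene Tfrc was at -2.54 and the lysosomal membrane gene Lamp2 at -2.16. Lamp1, with partly shared reads, and Slc3a2 were at -0.70 and -0.07. The median of this group, -1.43, lay at percentile 0.12 of random lists and at percentile 1.21 of those of named genes.

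Genes of the G2 phase and mitosis had ratios on the other side of 0 in the same comparison. Top2a had a log2 ratio of 0.97, Cenpa 0.75 and Kif2c 0.67, with a median at percentile 90.3, inside the central 95% of random lists. Of the 5 S phase genes, Cdc6 and Cdt1, which load the replicative helicase, were each at -1.12, Tk1 was at -0.53, and Pcna and Cdc45 were at -0.17 and -0.05, with a median of -0.53 at percentile 14.5. Tubb4b, at 1.34, was the only tubulin gene of 6 past the 2-fold line, and the tubulin median of 0.15 lay at percentile 55.6. Actb was lower by a factor of 3.38 (3.22 to 3.55) and Eef1a1 by 1.87 (1.80 to 1.94), whereas Eef2 had a log2 ratio of 0.18. Reads of Actb and Eef1a1 were partly shared with other transcripts, which their intervals do not cover. Ribosomal protein genes included Rps4x at -0.57 and Rps2 at -0.49, and their median of -0.06, at percentile 22.1, turned to 0.00 under median of ratios scaling. Heat shock genes had a median of -0.06 at percentile 34.0, with Hspa8 at -0.62. Srebf2 was at -1.66 and Insig1 at -0.44. Bax, Ndufa1 and Fxr1 were at -0.05, 0.38 and 0.19.

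Across 13059 compared transcripts, 1921 were at least 2-fold higher and 2712 at least 2-fold lower in midbodies than in interphase microtubules, and 404 and 544 at 4-fold, where a pseudocount of 0.1 turned the balance to 895 higher and 815 lower. The counting interval excluded 1 for 1891 and 2690 of them. Unchanged libraries gave mean counts of 19.6 and 31.2. The 3 libraries were not matched on preparation, since the labels give interphase cells no release from thymidine, nocodazole, shake-off or fresh medium. A pseudocount of 5 left 1091 transcripts in the higher group, and a floor of 10 RPKM left 1278. The transcript XM_003505339.1 (human protein match Q99983), chosen after its value was seen, had 273 midbody reads against 5 in interphase, a ratio of 135 with an interval of 57.0 to 418.

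**Figure D2:**
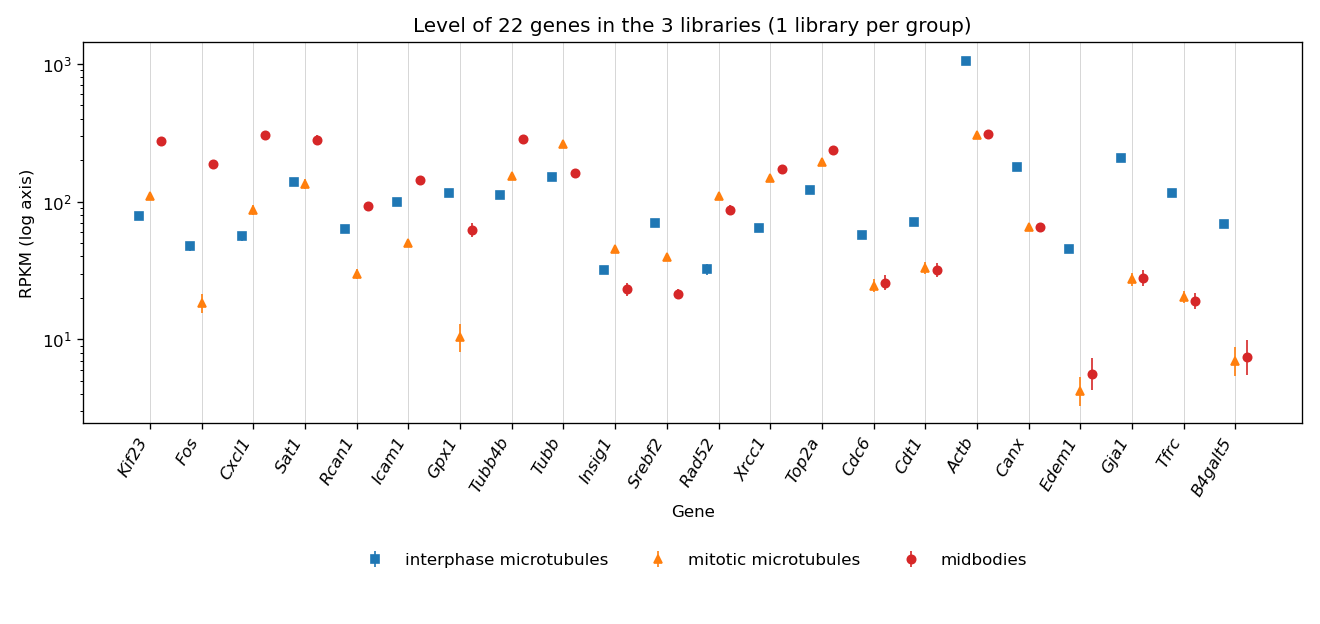
Levels of 22 named genes in RPKM on a log axis, with squares for interphase microtubules, triangles for mitotic microtubules and circles for midbodies, 1 library each, and bars for exact Poisson 95% intervals on the reads, which cover counting error only. Kif23, Fos, Cxcl1, Sat1, Rcan1, Icam1, Tubb4b, Xrcc1 and Top2a are highest in midbodies. Actb, Canx, Edem1, Gja1, Tfrc, B4galt5, Gpx1, Srebf2, Cdc6 and Cdt1 are highest in interphase, and Tubb, Insig1 and Rad52 in the mitotic library.

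Kif23, Fos, Cxcl1 and Sat1 were the 4 named genes at least 2-fold higher in midbodies than in both other libraries. The smaller of the log2 ratios was 1.97 for Fos, 1.79 for Cxcl1, 1.32 for Kif23 and 1.02 for Sat1, which fell to 0.995 with a pseudocount of 5. Next came Slc20a1 at 0.92, Tubb4b at 0.91, Pex5, a peroxisomal import receptor gene, at 0.82, Ankrd1 at 0.67 and Dnase1l1, a DNase-like gene, at 0.56. Over all transcripts, 99 met this rule, against 40.9 for independent lists of these sizes and a mean of 6.87, with a maximum of 13, in draws of unchanged libraries. Both ratios contain the midbody library, so part of the excess may come from that shared library. The count was 191 with a pseudocount of 0.1 and 36 with a pseudocount of 5. At least 2-fold lower than in both were 54 transcripts, against 33.9 for independent lists and 13.3 in the draws.

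Between mitotic and interphase microtubules, Rad52 was 3.40-fold higher in the mitotic library (3.06 to 3.79) and Xrcc1 2.31-fold (2.16 to 2.46). Slc25a32, a mitochondrial folate carrier gene, and Fpgs, which encodes the enzyme that adds glutamate to folates, were higher by 2.69-fold (2.43 to 2.99) and 2.38-fold (2.12 to 2.68). Kif23 was 1.38-fold higher (1.31 to 1.45), whereas Fos was lower by a factor of 2.59 (2.18 to 3.08). Slc31a1 was lower by a factor of 13.2 (8.93 to 20.4), Gpx1 by 11.1 (8.78 to 14.2), Edem1 by 10.7 (8.37 to 13.9) and B4galt5 by 9.99 (7.85 to 12.9).

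Of 258 named genes past the floor in this comparison, 11 were at least 2-fold higher and 79 at least 2-fold lower in the mitotic library. Cxcl3, Slc10a2, Csr1 and the drug efflux pump gene Abcb1b had log2 ratios of 2.48, 2.48, 1.84 and 1.26, all with reads partly shared with other transcripts, and the TFIID subunit gene Taf7 had 1.20. The low end also held Gna11 at -3.19, Sec22b at -2.97, Selenop, a secreted selenoprotein gene, at -2.91, Gja1 at -2.87, Gnai1 at -2.76 and Pea15, a death effector domain gene, at -2.75. Secreted and membrane protein genes had a median of -1.48 at percentile 0.12, and at percentile 1.04 of random lists of named genes, with Tfrc at -2.46 and Lamp2 lower by a factor of 4.16 (3.60 to 4.82). The endoplasmic reticulum stress genes had a median of -0.72 at percentile 2.05, but at percentile 18.4 of random lists of named genes, with 3 of 8 at least 2-fold lower.

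Top2a, Kif2c and Cenpa had mitotic to interphase log2 ratios of 0.69, 0.55 and 0.47, with a median at percentile 88.0. Cdc6 and Cdt1 were at -1.19 and -1.07, and the S phase median of -0.70 lay at percentile 9.89. Hspa8 and Hsph1 were at -0.89 and -0.88 and Hsp90aa1 at -0.02, which put the heat shock median of -0.88 at percentile 3.92. Insig1 was at 0.50 and Srebf2 at -0.80. Of the tubulin genes, 3 were higher and 3 lower, from Tubb at 0.79 to Tubb6 at -0.41, with a median of 0.10 at percentile 65.4. The ribosomal protein genes had a median of -0.23 at percentile 23.1, with Rps2 at -0.93. Actb and Eef1a1 were at -1.80 and -1.03, and Eef2, Ndufa1, Bax and Fxr1 at 0.04, -0.26, -0.35 and 0.13.

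Across 13176 compared transcripts, 2183 were at least 2-fold higher and 2725 at least 2-fold lower in the mitotic than in the interphase library, and 481 and 606 at 4-fold, where a pseudocount of 0.1 turned the balance to 1072 higher and 861 lower. Unchanged libraries gave mean counts of 11.1 and 14.8, and the counting interval excluded 1 for 2159 and 2712 of the transcripts. The median log2 ratio was -0.13 over all transcripts, 0.06 without the expression filter, and -0.50 over those with a symbol. A pseudocount of 5 left 1196 transcripts in the higher group. The division-stage libraries departed from interphase in many of the same transcripts: among the 12910 transcripts compared in both, 1560 of the 1859 higher in midbodies were also higher in the mitotic library, and 2153 of the 2712 lower in midbodies were also lower. Independent lists would share 293 and 572, and draws of unchanged libraries 1.98 and 3.52 on average. Because the interphase library enters both comparisons and cannot be split, part of the excess may come from it.

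**Figure D3:**
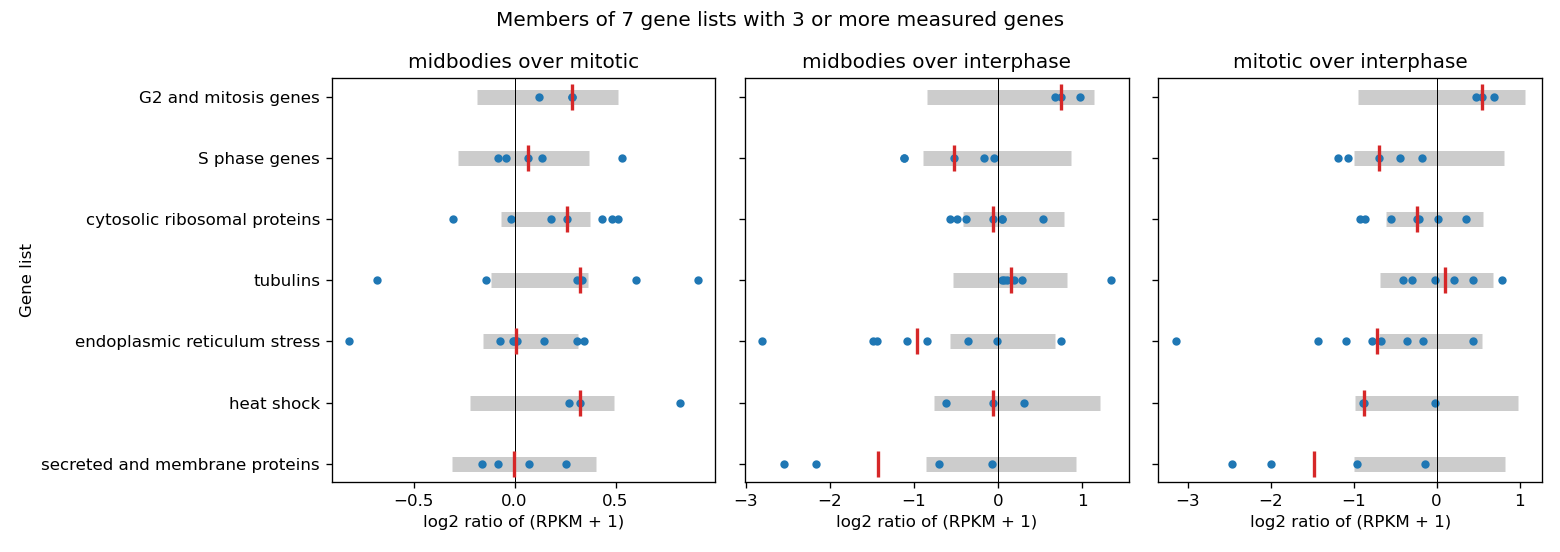
Log2 ratios of RPKM + 1 for each measured member (blue points) of 7 preset gene lists with at least 3 members, in the 3 comparisons, with the list median (red bar) and the central 95% of medians of 10000 random lists matched on expression (grey band). The medians of endoplasmic reticulum stress, -0.97 and -0.72, and of secreted and membrane proteins, -1.43 and -1.48, lie below their bands in the comparisons of midbodies and of mitotic microtubules with interphase.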

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

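Each result came from 1 library per group, so no replicate could be left out. No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers. The counts of 2-fold differences depended on the treatment of low transcripts. With a pseudocount of 0.1, midbodies had 458 transcripts higher and 479 lower than mitotic microtubules and 191 above both other libraries. With a pseudocount of 5 these were 99, 31 and 36, and the higher counts against interphase were 1091 for midbodies and 1196 for mitotic microtubules. With a filter at 10 RPKM they were 174, 81 and 62, and 1278 and 1399. Both settings act on low values by construction. The higher share of the midbody to mitotic calls, 53.6% in the main setting, was 76.2% with pseudocount 5 and 68.2% with the filter.

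With transcripts that have a symbol only, which tests fewer transcripts, the higher and lower counts were 8 and 1 for midbodies against mitotic, 21 and 86 for midbodies against interphase, and 17 and 84 for mitotic against interphase, with 4 above both. The higher share against interphase was then 19.6% and 16.8%, in place of 41.5% and 44.5%. The 2 other scalings and CPM kept all of these counts within 1.5 times. Without a filter the counts were the same by construction, since a 2-fold ratio with a pseudocount of 1 needs at least 1 RPKM. The 2 other scalings moved the median of all transcripts by at most 0.0567 on the log2 scale. Without the filter that median turned from -0.15 to 0.02 for midbodies against interphase and from -0.13 to 0.06 for mitotic against interphase.

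Lists with medians outside the central 95% of random lists numbered 1, 2 and 2 in the order midbodies to mitotic, midbodies to interphase and mitotic to interphase. With CPM, midbodies to mitotic gave 3, adding tubulins and ribosomal proteins, and mitotic to interphase gave 1, losing endoplasmic reticulum stress. Unmatched random lists gave 2, 1 and 1. Random lists of transcripts with a symbol gave 1 for midbodies to interphase, where endoplasmic reticulum stress was lost. In mitotic to interphase that setting gave 3 lists, among them G2 and mitosis genes at percentile 98.5 and secreted and membrane proteins at 1.04. Matching on length, an alternative chosen after seeing the data, gave the main counts, but heat shock genes, at percentile 2.17, took the place of endoplasmic reticulum stress in mitotic to interphase. The cause was not tested.

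No gene ratio past 2-fold and no list median outside the central 95% changed sign. These settings could hardly have changed one, since a pseudocount cannot turn the sign of a gene's ratio and the scalings shifted ratios little. The unchanged signs are therefore no check of these results. Of the quoted gene ratios, 323 values stayed within their counting interval and 32 moved, 30 of these with pseudocount 5. Of the list medians 191 stayed within theirs and 1 moved. The 4-fold counts stayed within 1.5 times in 31 cases and moved beyond in 17. Of the 31, 6 were counts without the filter, which could not change. Unmatched and length-matched random lists give no value for single genes, and the filters none for their ratios.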

Other observations

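The gene groups in this part were written after the gene names and the extreme ratios had been seen, and the tests of depth, of a filter, of transcripts with 10 or more reads, of shared handling and of endoplasmic reticulum binding were chosen only after the results were seen. Selenoprotein genes were higher in midbodies than in mitotic microtubules for 12 of 15 members, with a median log2 ratio of 0.47 that exceeded those of all 10000 random lists. Gpx1 led with 2.49, followed by Gpx3 at 0.78 from levels under 3 RPKM, Selenom at 0.75, the lipid peroxidase gene Gpx4 at 0.74 and Selenof at 0.64. Without the members whose values had been seen, 13 remained with a median of 0.33 at percentile 99.7, and at percentile 97.8 of random lists of named genes. Against interphase, 5 of these 13 were at least 2-fold lower in the mitotic library, with a median of -0.62 at percentile 20.02 of random lists of named genes. In midbodies, 9 of the 15 members were below interphase and 6 above, with a median of -0.47 at percentile 38.4 of such lists. Gpx1 stood at 62.6 RPKM in midbodies, 10.3 in the mitotic library and 115 in interphase.

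Of 8 apoptosis genes, 6 were at least 2-fold lower in midbodies than in interphase, among them the caspase genes Casp2 and Casp9 at -2.40 and -1.99 and the survival gene Bcl2l1 at -2.09, while Bax and Casp8 were at -0.05 and -0.15. The median of -1.87 lay at percentile 0.03 of random lists and at percentile 0.74 of random lists of named genes. In the mitotic library 5 of 8 were at least 2-fold lower, with a median of -1.94 at percentile 0.395 of random lists of named genes. Of the 5 G protein subunit genes whose values had not been seen, 3 were at least 2-fold lower in midbodies, with a median of -1.29 at percentile 0.545 of random lists of named genes. The 23 DNA replication and repair genes had a median of -0.05 at percentile 57.1, with Xrcc1 at 1.42 and Cdc6 at -1.12. The 5 peroxisome assembly genes had a median of -0.57 at percentile 22.4, from Pex5 at 0.92 to Pex19 at -2.30.

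The interphase library was the deepest yet listed the fewest transcripts with at least 1 read, 15357 against 16072 in midbodies and 17292 in the mitotic library. Depth was argued against, since interphase still had 9.85% fewer than midbodies after thinning to equal reads, and a filter by the authors was argued against by 2291 transcripts above 0 and under 5 reads in interphase. Over the 5971 transcripts at 0 in interphase, an even background of reads, as genomic DNA might give, predicted 3953 at 0 in midbodies. The observed number was 4322, a ratio of 1.09. With so few midbody reads most transcripts were predicted at 0 in any case, so this measure could hardly go against a background. It left the midbody library open, and the mitotic ratio of 1.33 fell between the bounds set and left that library open too. A strictly even background would fall short of the 80 mitotic and 16 midbody transcripts with 10 or more reads, which were 12.996 and 69.5 times the expected numbers. A background that varies between transcripts was not tested. Lengths of the 2815 transcripts without reads in any library were set to the median, and no biological explanation was tested.

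The midbody and mitotic libraries resembled each other far more than either resembled interphase. A trend with transcript length was argued against as the whole cause. After removing it, the number of 2-fold differences between midbodies and interphase was 98.8% of that before. There Spearman's rho of the ratio with length was 0.0128, but the trend was not monotonic. Median log2 ratios of length bins were 0.15 at a median length of 351, -0.32 at 1128 and -0.005 at 6603. Between midbodies and mitotic microtubules rho was -0.172, so short transcripts ran higher in midbodies, and removing the trend gave 491 2-fold differences in place of 511. Counting noise gave 1.10% of the 2-fold differences between midbodies and interphase. The shared handling of the mitotic and midbody cells, nocodazole and shake-off, cannot be told apart from the stage of division, because 0 libraries had only 1 of these steps. Release from thymidine and fresh medium, which both preparations also had and interphase lacked, cannot be told apart from it either. The stage of division itself, and the GC content of the transcripts, stayed untested.

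Solute carrier and glycosylation genes had medians below 0 against interphase, in the mitotic library -0.56 at percentile 13.02 and -0.73 at percentile 2.79, both inside the central 95% of random lists. Of 16 solute carrier genes, 7 were at least 2-fold lower and 3 higher in midbodies, with a median of -0.82 at percentile 3.18, and of 21 glycosylation and GPI anchor genes, 9 were lower and 0 higher, with a median of -0.85 at percentile 2.12. Among named genes alone these medians lay at percentiles 71.8 and 41.9, so neither group stood out from named genes of similar expression. That pool of 282 transcripts is small and includes the members themselves, and its median over all expression levels was -0.49. Over the 28 members not seen before, removing the length trend left a median of -0.73, from -0.89, which argues against length as the whole cause. A candidate explanation is that RNAs of membrane and secretory proteins sat on endoplasmic reticulum that copurified with interphase microtubules. Among named genes, the preset list of secreted and membrane proteins lay at percentile 1.21 and that of endoplasmic reticulum stress at 3.25. Only the first was outside the central 95%, which decides neither way. The apoptosis genes, mostly of cytosolic proteins, had a lower median still.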
